A study of Mus musculus with 20 samples.

How the data were processed

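RNA of 20 ID8 tumours from 20 female mice was measured by sequencing, with 3 or 4 animals in each of 6 treatment groups. Per the labels, total RNA came from frozen tissue, and stranded whole-transcriptome libraries were made with depletion of what the labels call cytoplasmic RNA. The authors aligned the reads to GRCm38 with STAR and counted them per gene with HTSeq, and the deposited count table holds whole-number read counts per Ensembl gene, not normalized. The labels give no tool versions, annotation release or strand setting. A second deposited table holds log2 values that the authors made from RPKM per coding sequence with 1 added before the logarithm. Checked on the files, each RPKM was proportional to the count of the same gene, with 1 factor per gene and 1 per library. The reads themselves were not used here.

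Tests ran on the counts of all 20 libraries in R 4.3.3 with edgeR 4.0.16. Of 55406 genes in the count table, 18144 passed filterByExpr with a minimum count of 10 and a minimum total of 15, and the genes left out held at most 0.0518% of the counts of a library. Symbols and positions were taken from GENCODE M21, where 55141 of the identifiers matched. Unmatched identifiers held 0.0450 to 0.0571% of the counts. Library totals ran from 26.9 to 34.7 M, and the 10 most abundant genes of a library took 5.47 to 10.8% of it. TMM factors ran from 0.958 to 1.03. The common biological coefficient of variation was 0.208. For genes with a mean of at least 50 counts, the spread between animals of a group exceeded counting noise, with a chi-squared per degree of freedom of 19.7 to 144. It was unequal between groups, at 19.7 to 24.2 in controls, 28.3 to 37.0 with PARPi and 50.8 to 144 in the full combination.

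The model held 1 coefficient per treatment group and no covariate, and quasi-likelihood F tests gave 11 contrasts, namely each of the 5 treatments against control, ICB or anti-VEGFA added to another treatment (4 contrasts), and 2 interactions. Replicate numbers recur across groups but the labels state no pairing, so they were not used as a block. The p-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. SE was the absolute log2 fold change divided by the square root of F. CPM used effective library sizes, and list scores are means of log2 CPM with a prior count of 2. A set of 36 gene lists with 404 genes, none in more than 1 list, was examined with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The contrasts, tests, lists and alternatives were chosen before the data were examined, except where the text says otherwise. Lists for cell types are read as RNA of those cells in bulk tissue, with no cell count implied. A further 3 lists were written after the data were seen.

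Genes named in the text follow a fixed rule. Among called genes with a mean of at least 1 CPM over the libraries compared and no overlap between the libraries of the 2 groups, a gap that chance alone gives to 10% of genes for 3 against 3, the 6 with the largest change each way may be named, leaving out unnamed gene models and immunoglobulin and T cell receptor segments. For interactions the condition on overlap was dropped. Where genes named by this condition are said below to lie apart in all libraries, the gap was part of their choice and is no further result. From each list up to 4 members with the smallest p may be named, and Parp1, Parp2, Cd274, Ctla4, Vegfa, Brca1 and Trp53 in any contrast. Genes outside the rule are marked where they appear.

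The alternatives were the size factors of DESeq2 in the same test, no filter on low counts, replicate number as a block, the Wald test of DESeq2 1.42.0, a fit of the compared groups alone, limma 3.58.1 with a trend on the deposited log2 RPKM values, and each library of the compared groups left out in turn. A fit without the 4 libraries in which acinar genes averaged above 2 log2 CPM was added after the data were seen. On simulated data with 200 changed genes in the PARPi contrast, edgeR recovered 89% of 2-fold and 100% of 4-fold changes with 5.03% false calls, and DESeq2 93% and 100% with 15.0% false calls. In the contrast of the full combination, edgeR recovered 87% and 99% with 7% false calls, and DESeq2 91% and 100% with 14.7%. The genes changed in the simulation all had a mean of at least 2 CPM, and each gene had the same dispersion in all groups. These shares therefore do not carry over to genes of lower level or to groups of unequal spread. The 3 list tests found a list shifted in simulated data and called 0 of 20 unchanged lists at an unadjusted p under 0.05. Each gene was drawn independently there, so the simulation cannot show how correlation between the genes of a list affects these tests.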

Results

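RNA was sequenced from 20 mouse tumours, read here as 1 per animal from the sample titles. The tumours grew after intraperitoneal injection of ID8 cells, a mouse ovarian surface epithelial cancer line, that per the labels lack Trp53, a tumour suppressor, and Brca1, a gene of homologous recombination repair. The 6 groups were untreated control tumours (n = 3), olaparib, an inhibitor of the repair enzyme PARP (PARPi, 40 mg/kg per day by mouth, n = 3), immune checkpoint blockade (ICB, 100 µg anti-CTLA-4 with 200 µg anti-PD-L1, n = 3), PARPi+ICB (n = 3), PARPi with 20 µg anti-VEGFA, an antibody against the angiogenic factor VEGFA (n = 4), and PARPi+ICB+anti-VEGFA, called the full combination (n = 4). Libraries were stranded whole-transcriptome libraries of bulk tissue, so that tumour, immune and stromal cells were read together. Total counts per library (M) were 29.3 to 31.4 in controls, 31.0 to 34.6 with PARPi, 30.2 to 32.5 with ICB, 31.2 to 34.7 with PARPi+ICB, 26.9 to 34.0 with PARPi+anti-VEGFA and 27.4 to 32.3 in the full combination. The test covered 18144 genes. Changes are given as log2 fold changes ± SE and levels as mean CPM (counts scaled to the size of the library) ± SD over the animals of a group. Gene positions are on GRCm38.

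Transcripts of Brca1 (ENSMUSG00000017146, chromosome 11, 101488764 to 101551955) and Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) were read at 18.5 ± 0.973 and 56.8 ± 1.96 CPM in controls. No tumour of another genotype was used here, and a transcript level does not show whether the protein is made. Parp1 and Parp2, which encode the targets of olaparib, stood at 281 ± 14.1 and 43.5 ± 2.29 CPM in controls. None of these 4 genes passed the edgeR test in any of the 11 comparisons, with a smallest edgeR adjusted p of 0.122 for Parp1, 0.751 for Parp2, 0.272 for Brca1 and 0.210 for Trp53.

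**Figure D1:**
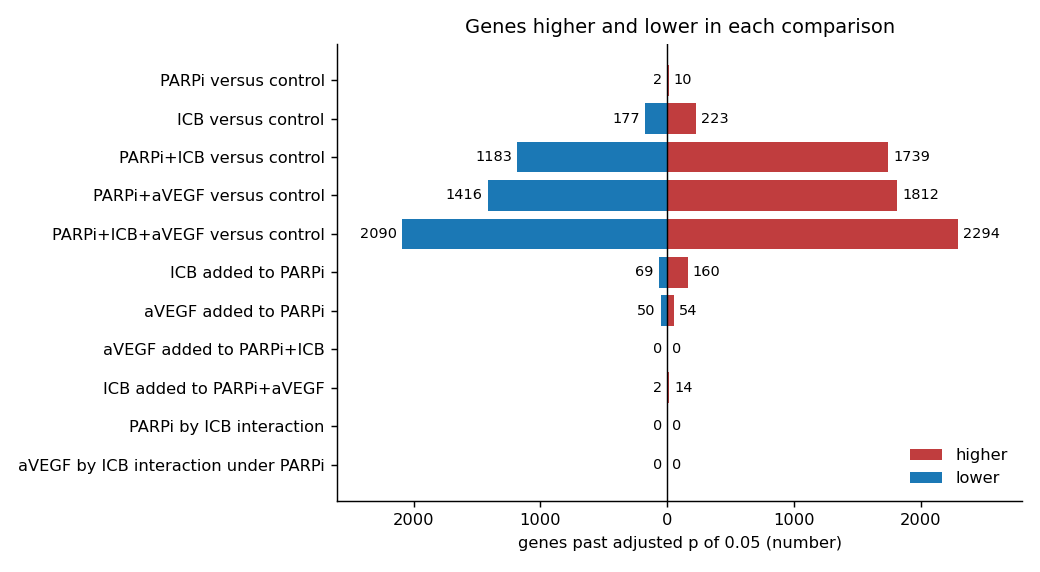
Numbers of genes past an edgeR adjusted p of 0.05 in each of the 11 comparisons, with bars to the right for genes higher and to the left for genes lower in the first-named treatment. The bars reach 2294 higher and 2090 lower genes for the full combination against control, and 0 for anti-VEGFA added to PARPi+ICB and for both interactions.

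The first comparison asked what PARP inhibition alone does to these tumours. Pou2af1 (ENSMUSG00000032053, chromosome 9, 51213708 to 51240080), a transcriptional coactivator of B cells and plasma cells, rose from 15.9 ± 2.16 to 50.2 ± 8.89 CPM, a log2 change of 1.66 ± 0.27. Ptprcap, a CD45-associated protein of lymphocytes, rose by 1.57 ± 0.26, Ly6d, a surface protein of early B lineage cells, by 1.19 ± 0.20, and the sialyltransferase St8sia6 by 1.26 ± 0.22. The septin gene Sept3 rose by 1.26 ± 0.22 and the zinc finger gene Zcchc18 from 0.348 ± 0.166 to 1.73 ± 0.207 CPM (log2 2.30 ± 0.37). Il23a, the p19 subunit of interleukin 23, fell by 1.40 ± 0.22. For these 7 genes, all 3 PARPi libraries lay on the same side of all 3 controls, and the edgeR adjusted p ran from 0.0330 to 0.0350.

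Genes of the type I interferon response, which cytosolic DNA sensing through STING can induce, had a positive log2 change for 23 of 23 members, with a median of 0.36, and 0 passed the edgeR test over all genes. By unadjusted p under 0.05 10 of them were higher, DESeq2 called 3 and limma on the deposited RPKM 0, and 5 were higher when adjusted over the list alone. Ifit2 stood at 83.8 ± 1.21 CPM against 50.3 ± 5.98 in controls (log2 0.74 ± 0.16, edgeR adjusted p 0.0825), Zbp1, a nucleic acid sensor, at 89.1 ± 3.25 against 56.4 ± 6.68 (log2 0.66 ± 0.19, edgeR adjusted p 0.158). Plasma cell genes had a median log2 change of 1.49 with 1 of 10 called (Pou2af1) and 9 higher when adjusted over the list alone. T cell genes had positive changes for 15 of 15 with a median of 0.58. Of these, edgeR called 0, 10 were higher by unadjusted p under 0.05, DESeq2 called 2 and limma 0, and 10 were higher when adjusted over the list alone. Against all other genes, camera adjusted p for these 3 lists ran from 7.73e-16 to 2.58e-11 with the preset correlation, while adjusted p ran from 0.0817 to 0.207 with an estimated correlation. Fry, which asks whether a list moves one way on balance, gave an adjusted p of 0.0255 for plasma cells and 0.0852 for both the interferon and the T cell genes. Skeletal muscle genes averaged 1.01 ± 1.57 log2 CPM with PARPi against 0.033 ± 0.15 in controls, with PARPi replicate 1 at 2.83.

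In all, edgeR called 12 genes, 10 higher and 2 lower, of 2065 with an unadjusted p under 0.05. DESeq2 called 338 and limma on the deposited RPKM 0. The count fell to 0 without control replicate 1 or 2 or PARPi replicate 1 or 2, to 4 without control replicate 3 and to 5 without PARPi replicate 3. Over these 6 fits, the edgeR adjusted p of the 7 genes named above ranged from 0.00528 for Ly6d to 0.207 for St8sia6. With 4 libraries of other groups that carry pancreatic acinar RNA left out of the fit, edgeR called 0. Of RNAs read as signs of library quality, chosen after their values were seen, Mir6236 stood at 53.5 ± 21.5 CPM with PARPi and 78.8 ± 2.90 in controls and Lars2 at 44.0 ± 8.12 and 70.7 ± 1.85. Rn7sk ran from 0.381 to 2.02 CPM with PARPi and from 1.83 to 4.16 in controls.

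Checkpoint blockade alone was compared with the same controls. Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), the constant region of the immunoglobulin mu heavy chain, rose from 1023 ± 338 to 5668 ± 2888 CPM, a log2 change of 2.47 ± 0.41 (edgeR adjusted p 0.00958). Pou2af1 rose by 1.60 ± 0.27. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), a secreted chitinase-like protein of alternatively activated macrophages, rose from 0.242 ± 0.144 to 18.8 ± 24.5 CPM (log2 6.27 ± 1.12, edgeR adjusted p 0.0124). Tap2, a subunit of the peptide transporter for MHC class I, rose by 0.51 ± 0.094. Pgc (ENSMUSG00000023987, chromosome 17, 47726842 to 47734482), which encodes pepsinogen C, fell from 39.8 ± 7.09 to 6.46 ± 3.20 CPM (log2 -2.62 ± 0.45, edgeR adjusted p 0.0102), and the annexin Anxa13 fell by 2.56 ± 0.49. For each of these 6 genes the 3 ICB libraries lay beyond all 3 controls.

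Plasma cell genes rose as a group, with 8 of 10 members called and a median log2 change of 1.61. Of these, 8 were higher when adjusted over the list alone. The plasma cell list moved one way by fry (adjusted p 0.00669), with a camera adjusted p of 5.74e-15 and an adjusted p = 0.0983 with an estimated correlation. The plasma cell count moved from 8 to 2 without control replicate 2 or ICB replicate 2, to 3 without control replicate 1 or ICB replicate 1 and to 5 without control replicate 3. Of the T cell genes 2 of 15 were called (median 0.71), of the genes of cytotoxic lymphocytes 0 of 12 (median 0.81) and of the interferon-gamma-inducible genes 1 of 14 (median 0.59). Of the T cell and interferon-gamma genes 12 and 12 were higher when adjusted over the list alone. Of the proliferation genes, 16 of 16 had negative changes with a median of -0.36. EdgeR called 0 of the cytotoxic and 0 of the proliferation genes, where 9 were higher and 9 lower by unadjusted p under 0.05. DESeq2 called 2 and 2, limma 0 and 0, and 9 and 9 passed when adjusted over the list alone. The T cell count moved from 2 to 0 without control replicate 1, 2 or 3 or ICB replicate 1, 2 or 3. The interferon-gamma count moved from 1 to 0 without control replicate 1, 2 or 3 or ICB replicate 1, 2 or 3. The proliferation count moved from 0 to 4 without ICB replicate 3. For the T cell, cytotoxic, interferon-gamma and proliferation lists, camera adjusted p ran from 1.30e-11 to 5.66e-07, adjusted p from 0.285 to 0.302 with an estimated correlation, and fry adjusted p from 0.0513 to 0.0738. Erythroid genes, from blood, averaged -0.77 ± 0.20 log2 CPM with ICB and 1.96 ± 1.42 in controls, with the highest control, replicate 2, at 3.45. With ICB Mir6236 stood at 31.0 ± 7.29 CPM, Lars2 at 37.4 ± 2.86 and Rn7sk at 0.337 ± 0.0848, each below all 3 controls in all 3 ICB libraries. Acinar genes averaged 3.36 log2 CPM in ICB replicate 3 and at most 0.63 in controls.

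For ICB alone against control edgeR called 400 genes, 223 higher and 177 lower, with 3200 at an unadjusted p under 0.05. With the mean log2 CPM of Rn7sk, Lars2 and Mir6236 as covariate, chosen after the results were seen, it called 0. Library quality and ICB cannot be told apart for these calls. DESeq2 called 1035 and limma on the deposited RPKM 254. The count was 182, 72 and 137 without control replicate 1, 2 and 3, and 148 and 106 without ICB replicate 1 and 2. Directions moved too, with 24 higher and 48 lower without control replicate 2, 56 higher and 81 lower without control replicate 3, 131 higher and 185 lower without ICB replicate 3 and 154 higher and 202 lower without the libraries with acinar RNA. Without control replicate 2 the edgeR adjusted p was 0.0505 for Chil3, 0.0543 for Tap2 and 0.0534 for Anxa13, while Ighm, Pou2af1 and Pgc stayed under 0.05 without any single library. Over all alternatives the adjusted p reached 0.493 for Chil3, 0.0593 for Anxa13 and 0.0504 for Pou2af1, and stayed under 0.05 for Ighm and Pgc. ICB replicate 3 held 47.1 CPM against 3.89 to 5.34 for Chil3, and without it the log2 change was 4.24 for Chil3 and -3.21 for Anxa13. Vegfa stood at 493 ± 36.9 CPM against 715 ± 88.3, with an edgeR adjusted p of 0.150.

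Tumours given PARPi+ICB held more RNA of immune cells than controls. Cd2 (ENSMUSG00000027863, chromosome 3, 101275899 to 101287939), an adhesion receptor of T cells, rose from 4.61 ± 0.914 to 16.2 ± 5.65 CPM (log2 1.82 ± 0.24, edgeR adjusted p 0.000172), and Lat, an adaptor of T cell receptor signalling, rose by 1.63 ± 0.20. Among genes of cytotoxic lymphocytes, Cd8b1, a chain of the CD8 coreceptor, rose by 1.41 ± 0.25, the transcription factor Eomes by 1.90 ± 0.28 and granzyme K, Gzmk, by 2.07 ± 0.45. Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832), which encodes a target of the antibodies, rose from 3.04 ± 1.23 to 8.24 ± 2.55 CPM (log2 1.43 ± 0.32, edgeR adjusted p 0.00607), and Foxp3, the transcription factor of regulatory T cells, by 1.34 ± 0.23. Ighm rose from 1023 ± 338 to 13879 ± 5051 CPM (log2 3.76 ± 0.44). Chil3 rose from 0.242 ± 0.144 to 208 ± 233 CPM, and Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a secreted protein of alternatively activated macrophages, from 0.556 ± 0.0186 to 86.9 ± 89.8 CPM, with edgeR adjusted p of 0.000136 and 0.000364. For Cd2, Ighm, Chil3 and Retnla all 3 libraries lay above all 3 controls. PARPi+ICB replicate 3 held 477 CPM against 69.0 to 78.5 for Chil3 and 190.4 CPM against 31.5 to 38.6 for Retnla. The log2 changes were 9.74 ± 1.18 and 7.28 ± 1.07, and 8.25 and 5.98 without that library.

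All 15 of 15 T cell genes rose (median log2 change 1.40), as did 10 of 12 genes of cytotoxic lymphocytes, 3 of 8 of natural killer cells, 9 of 10 of plasma cells (median 2.24) and 9 of 11 of macrophages, with the complement gene C1qa up by 0.68 ± 0.11. Of the antigen presentation genes, 8 of 11 for MHC class I and 8 of 9 for MHC class II rose, H2-K1 by 0.61 ± 0.13 and H2-Ab1 by 0.70 ± 0.13. Of the fibroblast and matrix genes 5 of 14 rose, among them the collagen crosslinking enzyme Lox by 1.01 ± 0.17. In these 8 lists, 15, 12, 5, 9, 10, 9, 9 and 7 genes were higher when adjusted over the list alone. The natural killer count moved from 3 to 0 without control replicate 1 or 3 or PARPi+ICB replicate 3 and to 1 without PARPi+ICB replicate 1. The macrophage count moved from 9 to 4 without PARPi+ICB replicate 3. The MHC class I count moved from 8 to 2 without PARPi+ICB replicate 3 and to 5 without control replicate 3. The MHC class II count moved from 8 to 2 without PARPi+ICB replicate 3, to 3 without control replicate 3, to 4 without control replicate 1 and to 5 without control replicate 2 or PARPi+ICB replicate 1. The fibroblast count moved from 5 to 3 without control replicate 2 or 3 or PARPi+ICB replicate 2 or 3. Camera adjusted p for these 8 lists ran from 2.22e-21 to 0.00170, adjusted p from 0.0819 to 0.319 with an estimated correlation, and fry adjusted p from 8.53e-05 to 0.0278.

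Genes of pericytes, the mural cells of small vessels, fell for 7 of 9 members (median -0.80), Rgs5 by 1.09 ± 0.23 and Mcam by 0.80 ± 0.18, and hypoxia genes for 5 of 13 (median -0.35). Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369), a hypoxia-induced angiogenic factor, fell from 715 ± 88.3 to 392 ± 116 CPM (log2 -0.87 ± 0.19, edgeR adjusted p 0.00546), and the pyruvate dehydrogenase kinase Pdk1 by 0.75 ± 0.14. When adjusted over the list alone, 9 pericyte and 7 hypoxia genes were lower. The pericyte count moved from 7 to 4 without PARPi+ICB replicate 1 or 3. The hypoxia count moved from 5 to 3 without control replicate 1 or PARPi+ICB replicate 1 or 3 and to 8 without PARPi+ICB replicate 2. The camera adjusted p was 2.01e-07 for pericytes and 5.35e-05 for hypoxia, adjusted p = 0.129 and 0.264 with an estimated correlation, and fry adjusted p 0.00148 and 0.0224. Of the epithelial and mesothelial genes of ID8 cells and peritoneum, 5 of 12 fell, among them Msln by 0.51 ± 0.093 and Krt7 by 0.96 ± 0.18, while 2 rose, Epcam by 1.75 ± 0.26 and Cdh1 by 0.86 ± 0.18. Of these 12, 8 were lower and 3 higher when adjusted over the list alone. The lower epithelial count moved from 5 to 3 without PARPi+ICB replicate 3. Pgc fell by 3.27 ± 0.47. The heat shock gene Hspa1a had a mean of 9.66 ± 15.1 CPM, with PARPi+ICB replicate 2 at 27.1, and its edgeR adjusted p of 0.00592 became 0.172 without that library.

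EdgeR called 2922 genes, 1739 higher and 1183 lower, of which 852 changed at least 2-fold (695 higher, 157 lower). The count was 1337 without PARPi+ICB replicate 3. Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), which encodes PD-L1, a target of the antibodies, rose by 0.67 ± 0.19 (edgeR adjusted p 0.0240), with 0.0812 and 0.0940 without control replicate 1 and 3, and 0.0558 and 0.0794 without PARPi+ICB replicate 1 and 3. Adipocyte genes averaged 1.88 ± 0.17 log2 CPM against 0.34 ± 0.053 in controls, and the non-coding RNA Mir6236 32.6 ± 7.57 CPM against 78.8 ± 2.90. Lars2 stood at 35.6 ± 3.68 against 70.7 ± 1.85 CPM, and Rn7sk ran from 0.436 to 0.865 CPM against 1.83 to 4.16. Erythroid genes averaged -0.49 ± 0.75 log2 CPM against 1.96 ± 1.42, with 3 of 8 called lower and 8 lower by unadjusted p under 0.05. Of the immediate early and heat shock genes 5 of 11 were called higher, at 4.54 ± 1.21 log2 CPM against 3.78 ± 0.17, with PARPi+ICB replicate 2 at 5.93.

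PARPi+anti-VEGFA was compared with untreated controls, so the changes here carry both drugs, and what anti-VEGFA adds to PARPi is asked in a comparison below. Cd2 rose from 4.61 ± 0.914 to 13.3 ± 2.44 CPM (log2 1.52 ± 0.23, edgeR adjusted p 0.000542), the CD8 chain Cd8a by 1.46 ± 0.27, granzyme A, Gzma, by 2.21 ± 0.40 and the activating receptor Klrk1 (NKG2D) by 1.18 ± 0.24. Pou2af1 rose from 15.9 ± 2.16 to 67.8 ± 19.7 CPM and the kappa light chain constant region Igkc by 1.95 ± 0.34 (edgeR adjusted p 0.00139). Over all alternatives the adjusted p of Igkc ran from 2.41e-06 to 0.0787. The acute phase gene Saa3 rose by 2.92 ± 0.65 and Lrg1, a secreted glycoprotein, by 2.89 ± 0.54. Col10a1 (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085), a collagen of hypertrophic cartilage, fell from 49.2 ± 9.28 to 6.40 ± 4.13 CPM (log2 -2.93 ± 0.53, edgeR adjusted p 0.00166), and the steroid hydroxylase Cyp17a1 by 2.11 ± 0.30. PARPi+anti-VEGFA replicate 4 held 147 CPM against 26.1 to 55.4 for Saa3, whose log2 change was 2.10 without it. All 4 treated libraries lay beyond all 3 controls for Cd2, Pou2af1, Saa3, Lrg1 and Col10a1.

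All 15 of 15 T cell genes rose (median 1.09), with 9 of 12 genes of cytotoxic lymphocytes, 8 of 8 of natural killer cells, 8 of 10 of plasma cells (median 1.68) and 9 of 11 of macrophages, among them C1qc by 0.70 ± 0.11 and the scavenger receptor Msr1 by 0.96 ± 0.17. Of the MHC class I genes 10 of 11 rose, B2m, the MHC class I light chain, by 0.50 ± 0.12. Interferon-gamma-inducible genes rose for 10 of 14, the guanylate-binding protein Gbp5 by 0.94 ± 0.20 and the chemokine Cxcl10 by 0.73 ± 0.18, and type I interferon genes for 6 of 23, Zbp1 by 1.02 ± 0.18 and Ifit2 by 0.81 ± 0.15. Cd274 rose by 0.76 ± 0.18. Fibroblast and matrix genes rose for 8 of 14, Lox by 1.02 ± 0.16 and Col1a2 by 0.71 ± 0.15. The 9 lists held 15, 10, 8, 10, 10, 10, 13, 14 and 10 higher genes when adjusted over the list alone. The cytotoxic count moved from 9 to 5 without control replicate 3. The natural killer count moved from 8 to 3 without control replicate 3 and to 5 without control replicate 1 or 2 or PARPi+anti-VEGFA replicate 3. The macrophage count moved from 9 to 5 without control replicate 3. The MHC class I count moved from 10 to 5 without control replicate 3 and to 6 without PARPi+anti-VEGFA replicate 3. The interferon-gamma count moved from 10 to 3 without control replicate 1 or 3, to 4 without PARPi+anti-VEGFA replicate 3 and to 5 without PARPi+anti-VEGFA replicate 4. The type I interferon count moved from 6 to 14 without PARPi+anti-VEGFA replicate 1. Camera adjusted p for these 9 lists ran from 3.91e-17 to 1.96e-06, adjusted p from 0.104 to 0.272 with an estimated correlation, and fry adjusted p from 0.000468 to 0.0211.

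Pericyte genes fell for 5 of 9 members (median -0.58, 6 lower when adjusted over the list alone), Rgs5 by 0.98 ± 0.21 and Higd1b by 1.47 ± 0.31, with a camera adjusted p of 2.19e-05, adjusted p = 0.140 with an estimated correlation and fry adjusted p 0.00252. The pericyte count moved from 5 to 3 without control replicate 2. Of 16 endothelial genes 0 were called higher and 1 lower, with 0 and 1 at an unadjusted p under 0.05. DESeq2 called 0 higher and 1 lower, limma 0 and 1, and adjusted over the list alone 0 were higher and 1 lower. Vegfa stood at 574 ± 68.8 CPM against 715 ± 88.3 in controls (log2 -0.32 ± 0.18, edgeR adjusted p 0.234). Of the epithelial and mesothelial genes 6 fell and 2 rose of 12, with 7 and 2 adjusted over the list alone, the log2 change of Msln at -0.65 ± 0.086 and of Epcam at 1.53 ± 0.25. The lower epithelial count moved from 6 to 3 without control replicate 1. Ctla4 rose by 1.10 ± 0.31 (edgeR adjusted p 0.0201), with 0.10, 0.0695 and 0.0534 without control replicate 3 and PARPi+anti-VEGFA replicate 3 and 4.

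EdgeR called 3228 genes, 1812 higher and 1416 lower, 745 of them at least 2-fold (605 higher, 140 lower). The count was 1991 without control replicate 3. Pancreatic acinar genes averaged 5.66 and 5.68 log2 CPM in PARPi+anti-VEGFA replicate 1 and 4, against at most 0.63 in controls. Adipocyte genes averaged 2.04 ± 1.10 against 0.34 ± 0.053 log2 CPM in controls. Mir6236 stood at 22.1 ± 4.76 CPM against 78.8 ± 2.90, and the small nuclear RNA Rn7sk fell by 2.78 ± 0.54. Lars2 stood at 30.3 ± 3.49 CPM against 70.7 ± 1.85, and erythroid genes averaged 0.11 ± 1.00 log2 CPM against 1.96 ± 1.42, with 3 of 8 called lower.

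The full combination was compared with controls next. Cd2 rose from 4.61 ± 0.914 to 17.5 ± 4.24 CPM (log2 1.93 ± 0.23, edgeR adjusted p 5.10e-05), Eomes by 2.04 ± 0.27, Gzma by 2.31 ± 0.40 and Ncr1, an activating receptor of natural killer cells, by 1.81 ± 0.44. Ctla4 rose from 3.04 ± 1.23 to 9.78 ± 1.62 CPM. Ighm rose from 1023 ± 338 to 9402 ± 3719.6 CPM (log2 3.20 ± 0.42), Chil3 from 0.242 ± 0.144 to 117 ± 32.9 CPM (log2 8.90 ± 1.15) and Retnla from 0.556 ± 0.0186 to 59.5 ± 30.1 CPM (log2 6.73 ± 1.04), with edgeR adjusted p of 8.14e-05, 7.51e-05 and 0.000297. Prg4, the lubricant proteoglycan, rose by 3.58 ± 0.86 and coagulation factor VII, F7, by 3.58 ± 0.69. Vegfa fell from 715 ± 88.3 to 347 ± 93.1 CPM (log2 -1.04 ± 0.18, edgeR adjusted p 0.000599) and Pgc by 2.86 ± 0.41. All 4 treated libraries lay beyond all 3 controls for Cd2, Ighm, Chil3, Retnla, Prg4, F7, Vegfa and Pgc.

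All 15 of 15 T cell genes rose (median 1.51), with 10 of 12 genes of cytotoxic lymphocytes, 8 of 8 of natural killer cells, 9 of 10 of plasma cells (median 2.15) and 9 of 11 of macrophages. Of the MHC class I genes 10 of 11 rose, of the MHC class II genes 8 of 9, H2-DMa, which loads peptides on class II molecules, by 0.66 ± 0.13, and of the interferon-gamma-inducible genes 8 of 14. Fibroblast and matrix genes rose for 9 of 14, lumican, Lum, by 1.85 ± 0.25 and decorin, Dcn, by 0.64 ± 0.15, while 1 fell. The 9 lists held 15, 12, 8, 9, 10, 10, 9, 9 and 9 higher genes when adjusted over the list alone. The natural killer count moved from 8 to 4 without control replicate 3. The MHC class II count moved from 8 to 5 without control replicate 1 or 3 or full-combination replicate 3. The interferon-gamma count moved from 8 to 0 without control replicate 1 or 3, to 1 without full-combination replicate 1 and to 3 without full-combination replicate 3. Camera adjusted p for these 9 lists ran from 2.63e-23 to 0.000215, adjusted p from 0.0920 to 0.333 with an estimated correlation, and fry adjusted p from 0.000126 to 0.0264. Cd274 rose by 0.66 ± 0.18 (edgeR adjusted p 0.0141), with 0.0573 and 0.0667 without control replicate 1 and 3.

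Hypoxia genes fell for 9 of 13 members (median -0.48), Pdk1 by 0.81 ± 0.13, the prolyl hydroxylase Egln3 by 0.70 ± 0.16 and Ndrg1 by 0.43 ± 0.094, and pericyte genes for 8 of 9 (median -0.73), Mcam by 0.78 ± 0.17. Adjusted over the list alone, 11 hypoxia and 8 pericyte genes were lower. The pericyte count moved from 8 to 2 without control replicate 2 and to 5 without control replicate 1 or full-combination replicate 1. Camera adjusted p was 6.82e-07 for hypoxia and 3.16e-05 for pericytes, adjusted p = 0.220 for both with an estimated correlation, and fry adjusted p 0.00298 and 0.00186. Of the endothelial genes 0 were called higher and 2 lower, with 2 and 3 at an unadjusted p under 0.05, 1 and 2 by DESeq2, 0 and 1 by limma, and 0 and 1 adjusted over the list alone. EdgeR called 4384 genes, 2294 higher and 2090 lower, 1121 of them at least 2-fold (928 higher, 193 lower), and 2877 without control replicate 2. Acinar genes averaged 7.97 log2 CPM in full-combination replicate 2, adipocyte genes 2.41 ± 0.48 over the 4 libraries, and Mir6236 56.8 ± 33.1 CPM. Lars2 stood at 44.8 ± 9.06 CPM, Rn7sk ran from 0.584 to 2.83 CPM, and erythroid genes averaged 0.64 ± 1.41 log2 CPM.

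**Figure D2:**
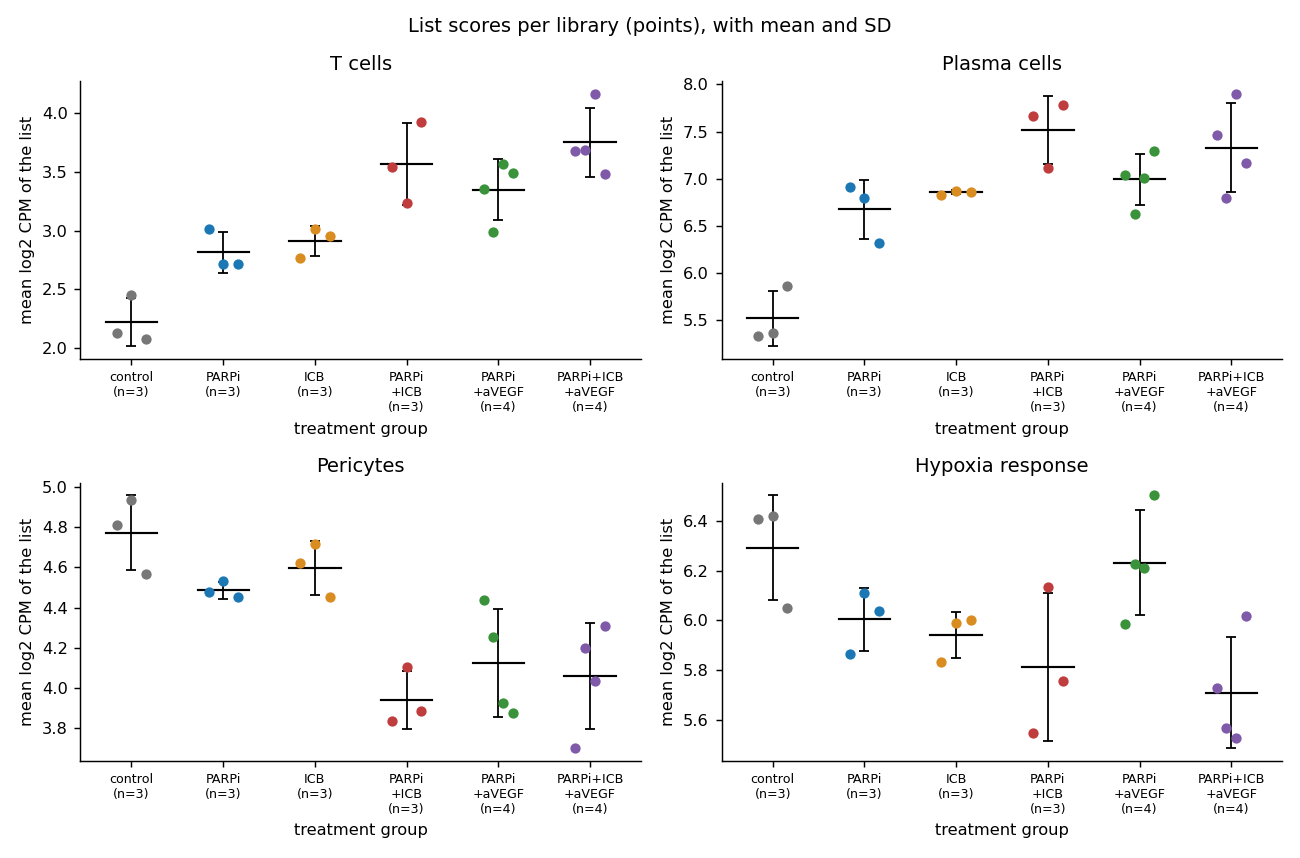
Mean log2 CPM of the genes of 4 lists in each library (points) by treatment group, with the group mean (long line) and SD (bars). T cell genes averaged 2.22 ± 0.20 in controls, 2.82 ± 0.17 with PARPi, 2.91 ± 0.13 with ICB, 3.57 ± 0.35 with PARPi+ICB, 3.35 ± 0.26 with PARPi+anti-VEGFA and 3.75 ± 0.29 in the full combination.

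**Figure D3:**
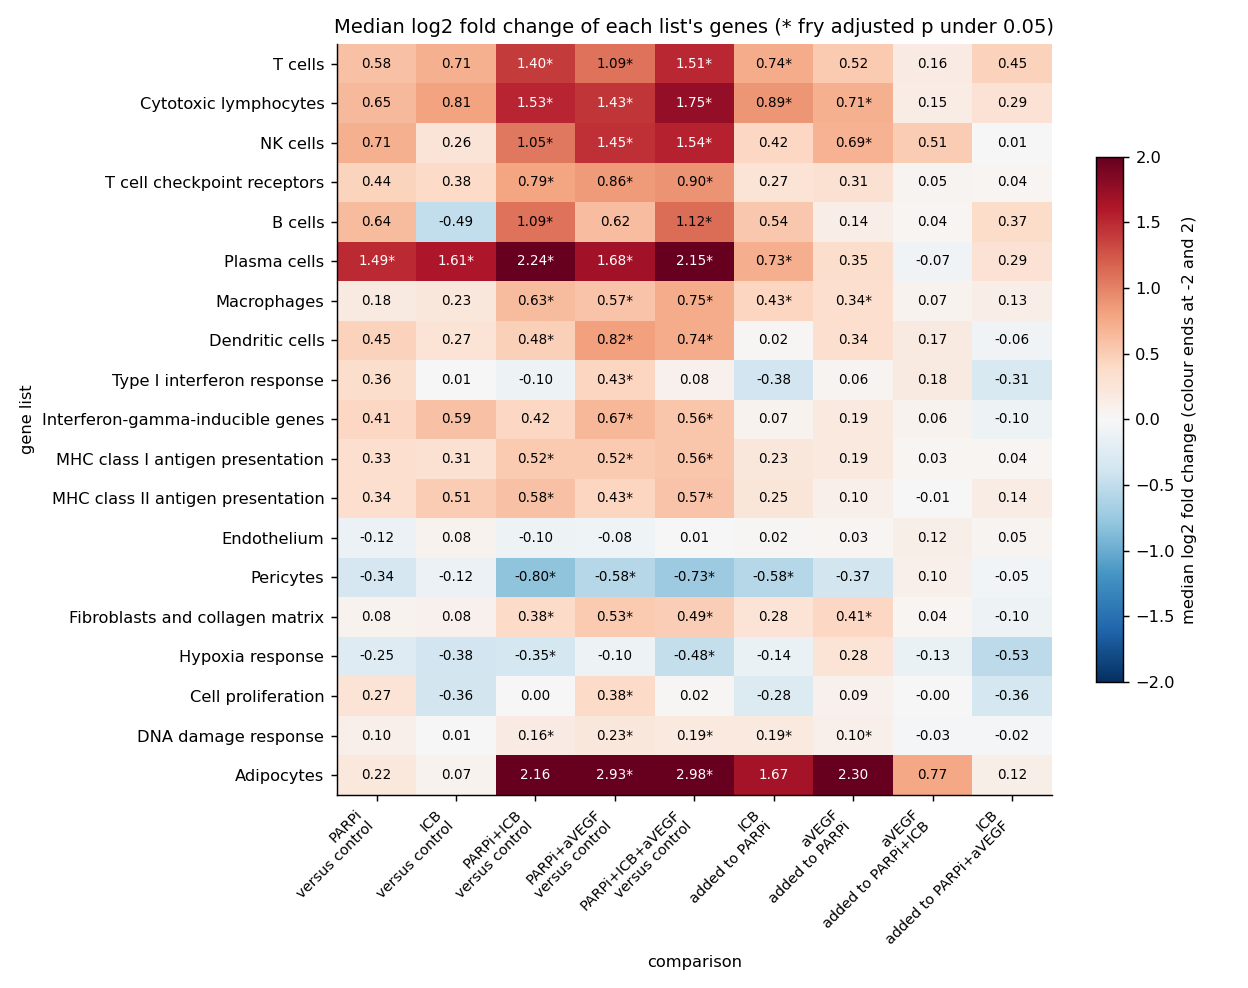
Median log2 fold change of the genes of 19 lists (vertical axis) in the 9 comparisons between groups (horizontal axis), with red for higher and blue for lower and a star where the fry adjusted p was under 0.05. In the 3 combination arms against control, T cell genes stand at 1.40, 1.09 and 1.51, and pericyte genes at -0.80, -0.58 and -0.73.

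To ask what checkpoint blockade adds to PARP inhibition, PARPi+ICB was compared with PARPi. Chil3 rose from 0.205 ± 0.0223 to 208 ± 233 CPM (log2 9.96 ± 1.19), Ighm from 1035 ± 249 to 13879 ± 5051 CPM (log2 3.74 ± 0.44) and Col6a5, a collagen VI chain, by 3.62 ± 0.57, with edgeR adjusted p of 0.00106, 0.00106 and 0.00537. Retnla rose from 2.07 ± 0.459 to 86.9 ± 89.8 CPM (log2 5.39 ± 0.94, edgeR adjusted p 0.0112) and Il5ra (ENSMUSG00000005364, chromosome 6, 106710357 to 106749037), the interleukin 5 receptor subunit of eosinophils and some B cells, from 0.315 ± 0.134 to 3.30 ± 1.28 CPM (log2 3.36 ± 0.58, edgeR adjusted p 0.0103). For these 5 genes all 3 PARPi+ICB libraries lay above all 3 PARPi libraries. Without PARPi+ICB replicate 3, which held 477 CPM against 69.0 to 78.5 for Chil3 and 190.4 CPM against 31.5 to 38.6 for Retnla, the log2 changes were 8.46 and 4.08. The RNA sensor Ifih1 fell from 62.0 ± 2.72 to 44.9 ± 2.83 CPM (log2 -0.47 ± 0.099) and the interferon-induced gene Ifi44 from 71.0 ± 1.29 to 41.6 ± 10.6 CPM (log2 -0.77 ± 0.19). The edgeR adjusted p of Retnla was 0.0523 without PARPi replicate 1, 0.0798 without PARPi replicate 2, 0.0732 without PARPi replicate 3 and 0.0610 without PARPi+ICB replicate 3. Il5ra had 0.0767 without PARPi replicate 2, 0.0558 without PARPi replicate 3 and 0.0524 without PARPi+ICB replicate 3. Ifih1 had 0.0648 without PARPi replicate 1, 0.0988 without PARPi replicate 2, 0.118 without PARPi replicate 3 and 0.186 without PARPi+ICB replicate 3. Ifi44 had 0.114 without PARPi replicate 1, 0.131 without PARPi replicate 2, 0.144 without PARPi replicate 3 and 0.265 without PARPi+ICB replicate 3.

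Of the T cell genes 4 of 15 rose (median 0.74), of the macrophage genes 1 of 11 (median 0.43), and of the type I interferon genes 2 of 23 fell, with 1 of 23 positive and a median of -0.38. Adjusted over the list alone, 15 T cell and 9 macrophage genes were higher and 14 type I interferon genes lower. The T cell count moved from 4 to 0 without PARPi replicate 2 or 3 or PARPi+ICB replicate 3 and to 2 without PARPi replicate 1. The macrophage count moved from 1 to 0 without PARPi replicate 2 or PARPi+ICB replicate 3, to 3 without PARPi+ICB replicate 1 and to 4 without PARPi+ICB replicate 2. The type I interferon count moved from 2 to 0 without PARPi replicate 1, 2 or 3 or PARPi+ICB replicate 3 and to 4 without PARPi+ICB replicate 2. By camera the adjusted p was 2.07e-15 for T cells, 2.25e-08 for macrophages and 9.89e-13 for type I interferon, adjusted p from 0.233 to 0.264 with an estimated correlation, and fry adjusted p 0.0433, 0.0433 and 0.0577. Vegfa stood at 392 ± 116 CPM against 587 ± 51.3 with PARPi (log2 -0.58 ± 0.19, edgeR adjusted p 0.134), and passed without PARPi+ICB replicate 2 (log2 -0.85, adjusted p 0.0339). EdgeR called 229 genes, 160 higher and 69 lower. The count was 62, 26 and 37 without PARPi replicate 1, 2 and 3, and 30 without PARPi+ICB replicate 3, with 53 higher and 9 lower in the first of these and 28 higher and 2 lower in the last. DESeq2 called 805 and limma on the deposited RPKM 104, and a fit of these 2 groups alone 118. Skeletal muscle genes averaged 1.01 ± 1.57 log2 CPM with PARPi and 0.19 ± 0.12 with PARPi+ICB, and adipocyte genes 0.64 ± 0.51 and 1.88 ± 0.17. Mir6236 stood at 53.5 ± 21.5 and 32.6 ± 7.57 CPM. Immediate early and heat shock genes averaged 3.82 ± 0.079 and 4.54 ± 1.21 log2 CPM, with PARPi+ICB replicate 2 at 5.93. By unadjusted p under 0.05 8 of 11 of them were higher and 6 of 7 muscle genes lower, where edgeR called 0 of each, DESeq2 2 and 2 and limma 0 and 0.

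Anti-VEGFA added to PARPi was compared with PARPi to ask what blocking VEGFA adds. Lox rose from 58.3 ± 1.57 to 113 ± 26.3 CPM (log2 0.95 ± 0.16), the matrix protein Cilp from 19.2 ± 5.74 to 46.5 ± 2.13 CPM (log2 1.28 ± 0.22), the matrix metalloproteinase Mmp3 by 2.22 ± 0.44 and the acute phase protease inhibitor Serpina3n by 1.25 ± 0.21. Col10a1 fell from 38.4 ± 16.1 to 6.40 ± 4.13 CPM (log2 -2.57 ± 0.53) and the membrane endopeptidase Mme by 0.85 ± 0.14. The edgeR adjusted p of these 6 genes ran from 0.0224 to 0.0395. All 4 PARPi+anti-VEGFA libraries lay beyond all 3 PARPi libraries for Cilp, Mmp3, Serpina3n, Col10a1 and Mme. Without PARPi replicate 2 the adjusted p of the 6 genes ran from 0.153 to 0.188. Without PARPi replicate 1 it was 0.0616 to 0.0658 for Lox and Col10a1. Without PARPi replicate 3 it was 0.0502 to 0.108 for Lox, Cilp, Serpina3n, Mmp3, Mme and Col10a1. Without PARPi+anti-VEGFA replicate 3 it was 0.0633 to 0.108 for Lox, Cilp, Serpina3n, Mmp3, Mme and Col10a1. Without PARPi+anti-VEGFA replicate 4 it was 0.0653 to 0.108 for Lox, Cilp, Serpina3n, Mmp3, Mme and Col10a1. Without PARPi+anti-VEGFA replicate 2 it was 0.0523 for Mmp3.

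Of the fibroblast and matrix genes 1 of 14 was called (Lox), with 13 positive and a median log2 change of 0.41. EdgeR called 0 of 11 macrophage genes (median 0.34) and 0 of 15 T cell genes (median 0.52), where 8 and 9 were higher by unadjusted p under 0.05, DESeq2 called 7 and 6 and limma 0 and 0. Adjusted over the list alone, 9, 8 and 9 of these genes were higher. The fibroblast count moved from 1 to 0 without PARPi replicate 1, 2 or 3 or PARPi+anti-VEGFA replicate 3 or 4 and to 3 without PARPi+anti-VEGFA replicate 1. The macrophage count moved from 0 to 2 without PARPi+anti-VEGFA replicate 1. Camera adjusted p for the 3 lists ran from 7.14e-10 to 3.41e-08, adjusted p from 0.175 to 0.190 with an estimated correlation, and fry adjusted p from 0.0357 to 0.0584. Vegfa stood at 574 ± 68.8 CPM against 587 ± 51.3 with PARPi alone (log2 -0.030 ± 0.18, edgeR adjusted p 0.961). Pericyte genes averaged 4.12 ± 0.27 log2 CPM with PARPi+anti-VEGFA (3.87 to 4.44) and 4.49 ± 0.041 with PARPi (4.45 to 4.53). Endothelial genes averaged 3.95 ± 0.12 and 3.901 ± 0.027, and angiogenic tip cell genes 3.57 ± 0.18 and 3.56 ± 0.052. At an unadjusted p under 0.05, 5 of 9 pericyte genes were lower and 0 higher. Of 16 endothelial, 10 tip cell and 13 hypoxia genes, 2, 2 and 4 were higher at that level and 0 lower. EdgeR called 104 genes, 54 higher and 50 lower, DESeq2 640 and limma on the deposited RPKM 9. The count was 17, 0 and 1 without PARPi replicate 1, 2 and 3, and 205, 33, 3 and 10 without PARPi+anti-VEGFA replicate 1, 2, 3 and 4. Adipocyte genes averaged 2.04 ± 1.10 log2 CPM with PARPi+anti-VEGFA and 0.64 ± 0.51 with PARPi, and Mir6236 22.1 ± 4.76 and 53.5 ± 21.5 CPM. Pancreatic acinar genes averaged 1.81 ± 4.46 and -2.08 ± 0.082 log2 CPM and skeletal muscle genes -0.0081 ± 0.054 and 1.01 ± 1.57. By unadjusted p under 0.05 11 of 13 acinar genes were higher and 5 of 7 muscle genes lower, where edgeR called 0 of each, DESeq2 8 and 1 and limma 0 and 0. Without the libraries with acinar RNA the count was 89, of which 41 were among the 104.

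Anti-VEGFA was also added on top of PARPi+ICB. Vegfa stood at 347 ± 93.1 CPM in the full combination and 392 ± 116 with PARPi+ICB (log2 -0.18 ± 0.18), Cd274 at 53.2 ± 11.7 and 53.6 ± 4.18, and Ctla4 at 9.78 ± 1.62 and 8.24 ± 2.55. Type I interferon genes had positive log2 changes for 23 of 23 members, with a median of 0.18 and none called, 0 higher when adjusted over the list alone, 1 by unadjusted p under 0.05, 0 by DESeq2 and 0 by limma. Camera adjusted p was 1.06e-06, 0.764 without PARPi+ICB replicate 3, and adjusted p = 0.722 with an estimated correlation. EdgeR called 0 genes, where 745 had an unadjusted p under 0.05 and the smallest adjusted p was 0.718. DESeq2 called 12 genes and limma on the deposited RPKM 2. The edgeR count was 1 without PARPi+ICB replicate 3. Immediate early and heat shock genes averaged 4.54 ± 1.21 log2 CPM with PARPi+ICB, PARPi+ICB replicate 2 at 5.93, and 3.78 ± 0.22 in the full combination, and acinar genes -1.84 ± 0.069 and 0.57 ± 4.93. By unadjusted p under 0.05 8 of 11 of the former were lower and 12 of 13 acinar genes higher, where DESeq2 called 0 and 3 and limma 0 and 0.

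ICB added to PARPi+anti-VEGFA was compared with that pair of drugs. Chil3 rose from 1.09 ± 0.475 to 117 ± 32.9 CPM (log2 6.77 ± 0.86, edgeR adjusted p 0.00555) and Ighm from 1844 ± 515 to 9402 ± 3719.6 CPM (log2 2.35 ± 0.36, edgeR adjusted p 0.0180). Retnla rose by 4.26 ± 0.77, Il5ra by 3.00 ± 0.50 and Tpsb2, a mast cell tryptase, by 1.78 ± 0.28, while the lysozyme gene Lyz1 fell by 1.34 ± 0.20, with edgeR adjusted p from 0.0180 to 0.0419. For these 6 genes all 4 libraries of the full combination lay beyond all 4 others. Without PARPi+anti-VEGFA replicate 2 the adjusted p of Chil3 was 0.0706. For the other 5 genes the adjusted p was 0.0542 to 0.0841 for Retnla, Il5ra, Ighm and Tpsb2 without PARPi+anti-VEGFA replicate 1, 0.0906 to 0.122 for all 5 without PARPi+anti-VEGFA replicate 2, 0.0601 to 0.0638 for all 5 without PARPi+anti-VEGFA replicate 3, 0.0890 to 0.120 for Retnla, Il5ra and Tpsb2 without PARPi+anti-VEGFA replicate 4. It was 0.0547 to 0.0592 for all 5 without full-combination replicate 1, 0.0539 to 0.0910 for Retnla, Il5ra, Ighm and Lyz1 without full-combination replicate 2 and 0.149 for Retnla without full-combination replicate 3.

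Hypoxia genes had negative changes for 13 of 13 members (median -0.53), type I interferon genes 2 positive of 23 (median -0.31) and T cell genes 15 of 15 (median 0.45). EdgeR called 0 in each of the 3 lists over all genes, where 11 hypoxia and 10 interferon genes were lower and 8 T cell genes higher by unadjusted p under 0.05. DESeq2 called 8, 3 and 0, and limma 0, 0 and 0. Adjusted over the list alone, 11, 7 and 7 passed. The hypoxia count moved from 0 to 2 without full-combination replicate 4. Camera adjusted p was 2.46e-17, 1.09e-10 and 3.68e-08, adjusted p = 0.207, 0.575 and 0.575 with an estimated correlation, and fry adjusted p 0.0589, 0.295 and 0.295. Vegfa stood at 347 ± 93.1 CPM against 574 ± 68.8 (log2 -0.73 ± 0.17, edgeR adjusted p 0.101), and passed without full-combination replicate 4 (adjusted p 0.0143, from 0.00691 to 0.370 over all alternatives). EdgeR called 16 genes, 14 higher and 2 lower, and DESeq2 261, 142 higher and 119 lower. By edgeR these were 37 higher and 26 lower with no filter, 31 higher and 23 lower with a replicate block and 42 higher and 30 lower without full-combination replicate 4. The count was 6, 0, 1 and 5 without PARPi+anti-VEGFA replicate 1, 2, 3 and 4, and 1, 3, 5 and 72 without full-combination replicate 1, 2, 3 and 4. Without the 4 libraries with acinar RNA it was 3, with an adjusted p of 0.160 for Ighm, 0.267 for Il5ra and 0.185 for Retnla. Mir6236 stood at 56.8 ± 33.1 CPM against 22.1 ± 4.76. Over all alternatives the adjusted p ran from 7.06e-07 to 0.160 for Ighm, 1.45e-06 to 0.267 for Il5ra and 1.82e-05 to 0.185 for Retnla.

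**Figure D4:**
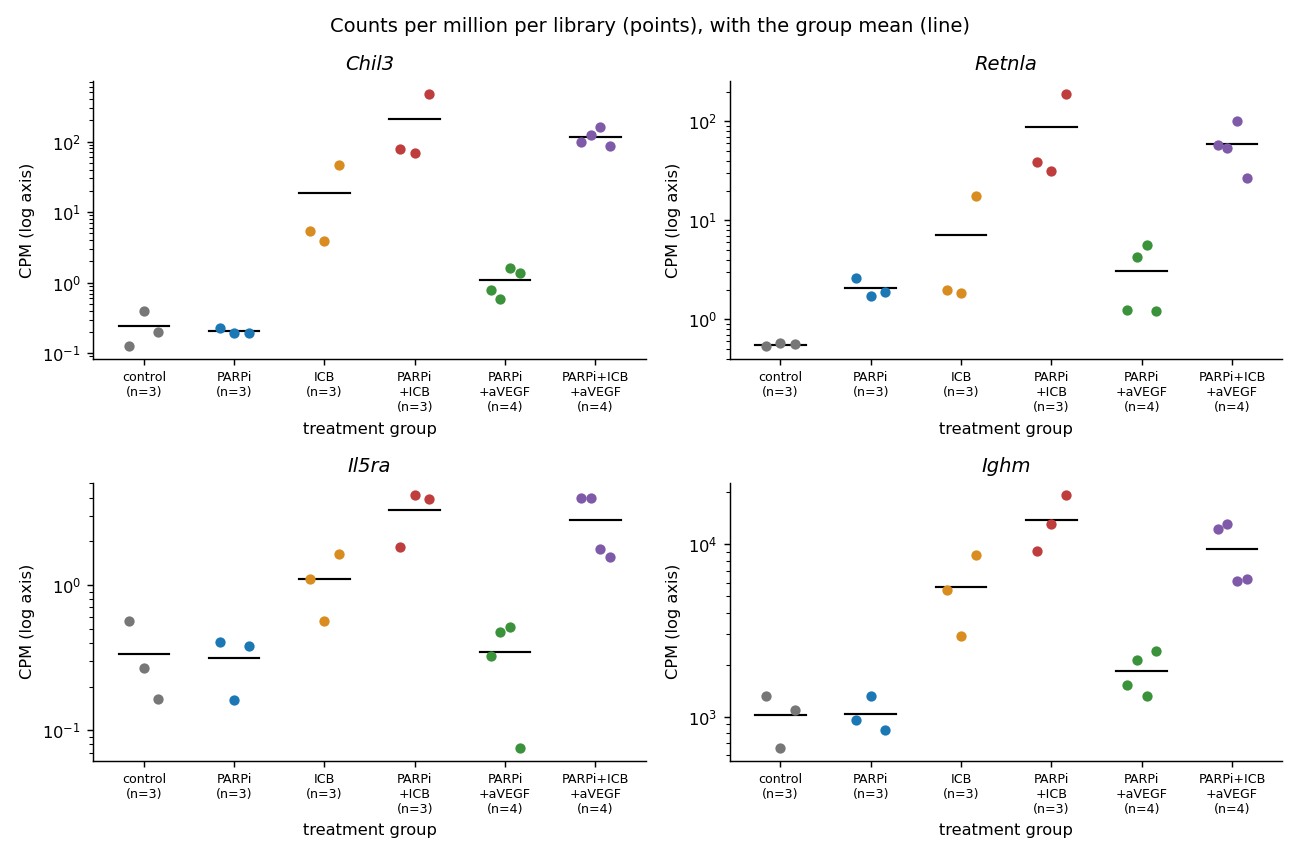
CPM of Chil3, Retnla, Il5ra and Ighm in each library (points) by treatment group, on a log axis, with the group mean as a line. Mean CPM of Chil3 was 0.242 ± 0.144 in controls, 0.205 ± 0.0223 with PARPi and 1.09 ± 0.475 with PARPi+anti-VEGFA, against 18.8 ± 24.5, 208 ± 233 and 117 ± 32.9 in the 3 groups given ICB, with ICB replicate 3 and PARPi+ICB replicate 3 far above the other libraries of their groups (47.1 CPM against 3.89 to 5.34, and 477 CPM against 69.0 to 78.5).

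Whether ICB acted differently with and without PARPi was tested as an interaction over the control, PARPi, ICB and PARPi+ICB groups. Type I interferon genes had negative interaction terms for 23 of 23 members, with a median of -0.43. Ifit2 stood at 50.3 ± 5.98 CPM in controls, 83.8 ± 1.21 with PARPi, 78.8 ± 15.3 with ICB and 64.4 ± 11.4 with PARPi+ICB (interaction -1.03 ± 0.23 on the log2 scale, edgeR adjusted p 0.869). None of the 23 passed over all genes, 10 were lower by unadjusted p under 0.05, DESeq2 called 1 and limma 0, and 2 were lower when adjusted over the list alone. Camera adjusted p was 1.50e-16, adjusted p = 0.668 with an estimated correlation, and fry adjusted p 0.710. The interaction term of Ighm was 1.27 ± 0.56 (edgeR adjusted p 0.958). EdgeR called 0 genes, where 946 had an unadjusted p under 0.05 and the smallest adjusted p was 0.869. DESeq2 called 7 and limma 0. By unadjusted p under 0.05 6 of 11 immediate early and heat shock genes were higher, DESeq2 called 0 and limma 0, with PARPi+ICB replicate 2 at 5.93 log2 CPM. The edgeR count was 2 without ICB replicate 3 and 1 without the 4 libraries with acinar RNA.

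The last comparison tested whether anti-VEGFA and ICB acted differently together than alone on a background of PARPi. Of the inflammatory genes driven by NF-kB, 1 of 15 had a positive interaction term and the median was -0.22, and of the DNA damage response genes 2 of 15, with a median of -0.14. None of these genes passed over all genes, 6 and 2 were lower by unadjusted p under 0.05, DESeq2 called 1 and 0, limma 0 and 0, and 2 and 0 were lower when adjusted over the list alone. For these 2 lists camera adjusted p was 2.54e-06 and 0.00745, adjusted p = 0.124 for both with an estimated correlation, and fry adjusted p 0.0873 and 0.0142. The interaction term of Vegfa was -0.15 ± 0.25 (edgeR adjusted p 0.954) and that of Cd274 -0.40 ± 0.25 (edgeR adjusted p 0.808). EdgeR called 0 genes, where 1188 had an unadjusted p under 0.05 and the smallest adjusted p was 0.456. DESeq2 called 15 and limma 0. By unadjusted p under 0.05 7 of 11 immediate early and heat shock genes were lower, with PARPi+ICB replicate 2 at 5.93 log2 CPM, and 4 of 7 muscle genes higher, with PARPi replicate 1 at 2.83. DESeq2 called 0 and 0 and limma 0 and 0 of these.

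**Figure D5:**
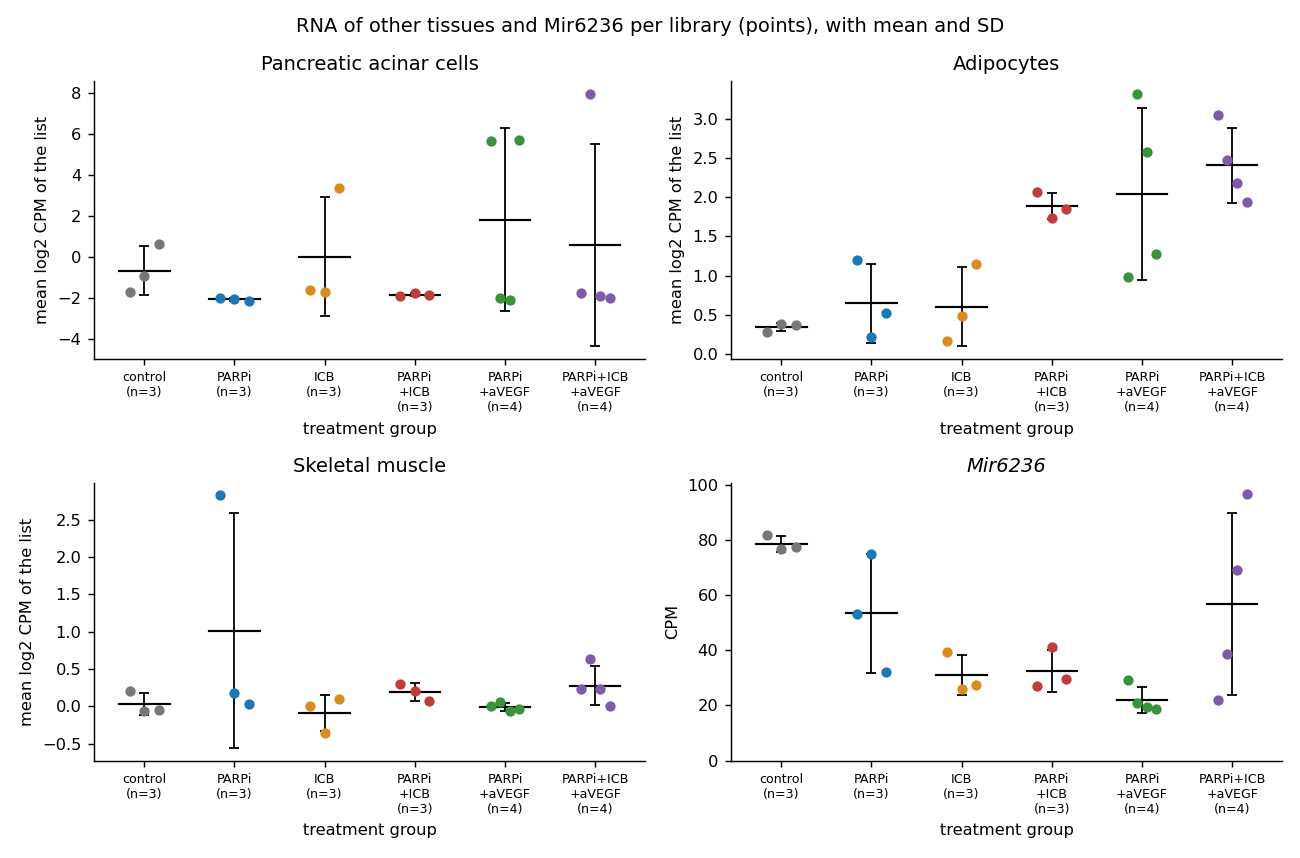
Mean log2 CPM of pancreatic acinar, adipocyte and skeletal muscle genes and CPM of the non-coding RNA Mir6236 in each library (points) by treatment group, with the group mean (long line) and SD (bars). Acinar genes averaged 3.36 in ICB replicate 3, 5.66 and 5.68 in PARPi+anti-VEGFA replicate 1 and 4 and 7.97 in full-combination replicate 2, and at most 0.63 in controls.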

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

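No test of this part was chosen after its result was seen, but some of the genes tested were picked for the text after their values were seen. In the 2 groups of 4 animals, the gap between the farthest library and its nearest neighbour, over the range of the group, was compared with the 95% critical value of Dixon's ratio for 4 values. Of 334 such tests, over the list scores and genes of the text, 12 passed, where chance alone gives about 1 in 20, or 16.7. Values here are log2 CPM.

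With PARPi+anti-VEGFA these were the dendritic cell genes in PARPi+anti-VEGFA replicate 3 (ratio 0.912, 3.69 against 3.31 to 3.35), the interferon regulatory factor Irf7 in PARPi+anti-VEGFA replicate 1 (ratio 0.880, 6.44 against 6.90 to 6.96), the hypoxia gene Car9 in PARPi+anti-VEGFA replicate 4 (ratio 0.888, 3.42 against 2.47 to 2.57) and, all in PARPi+anti-VEGFA replicate 2, Igkc (ratio 0.885, 13.51 against 14.23 to 14.32), the plasma cell gene Derl3 (ratio 0.923, 3.98 against 4.74 to 4.80) and Trp53inp1 (ratio 0.830, 7.37 against 7.92 to 8.03). In the full combination they were Sept3 in full-combination replicate 4 (ratio 0.844, 1.70 against 1.98 to 2.03), Cxcl10 in full-combination replicate 1 (ratio 0.886, 6.48 against 5.79 to 5.87) and the T cell gene Cd6 in full-combination replicate 3 (ratio 0.857, 3.84 against 3.37 to 3.44). In full-combination replicate 2 they were the acinar genes (ratio 0.972, 7.97 against -2.03 to -1.75), the intestinal genes (ratio 0.879, 1.13 against 0.46 to 0.54) and the epithelial and mesothelial genes (ratio 0.886, 6.07 against 6.38 to 6.42).

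Of 72 list tests of a difference between groups, in the 2 interactions, 1 had a fry adjusted p under 0.05, the DNA damage response genes in the interaction of anti-VEGFA and ICB under PARPi (0.0142). Their median interaction was -0.14, 2 of 15 were positive, and adjusted p = 0.124 by camera with an estimated correlation. No explanation was tested for this difference.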

How the results depend on the processing

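The alternative without the 4 libraries with acinar RNA was chosen after the data were seen. Of 1773 values of named genes under alternatives other than a left-out library, 1677 kept their direction and side of the threshold, 79 lost a call, 17 gained a call and 0 reversed. With 1 library left out, 1500 of 1713 were the same, 211 lost, 2 gained and 0 reversed. With the size factors of DESeq2, 254 of 254 were the same. Of 189 list calls, 0 held with an estimated correlation and 74 with fry. With 1 library left out, 1275 of 1449 values of these calls held and 174 were lost. Under the remaining alternatives 724 of 756 held.

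With no filter, edgeR called 70 genes for PARPi (12 with the filter) and 63 for ICB added to PARPi+anti-VEGFA (16). DESeq2 called 338 for PARPi, 1035 for ICB (400), 805 for ICB added to PARPi (229), 640 for anti-VEGFA added to PARPi (104), 12 for anti-VEGFA added to PARPi+ICB (0 by edgeR), 261 for ICB added to PARPi+anti-VEGFA, and 7 and 15 for the interactions of ICB with PARPi and with anti-VEGFA (0 and 0 by edgeR). In groups fitted alone, edgeR called 171 for PARPi and 118 for ICB added to PARPi. On the deposited RPKM, limma called 0 for PARPi, 254 for ICB, 104 for ICB added to PARPi, 9 for anti-VEGFA added to PARPi, 2 for anti-VEGFA added to PARPi+ICB and 10 for ICB added to PARPi+anti-VEGFA. For ICB these were 107 higher and 147 lower, against 223 and 177 by edgeR. Without the libraries with acinar RNA, edgeR called 0 for PARPi, 3 for ICB added to PARPi+anti-VEGFA and 1 for the interaction of PARPi and ICB. Replicate number as a block gave 20 for PARPi and 54 for ICB added to PARPi+anti-VEGFA. Libraries of the same number correlated after removal of group means with a median r of 0.00884 over 46 pairs, against -0.00951 over 120 other pairs. The fits without a filter test more genes and those of the groups alone or without libraries hold fewer samples. Fewer samples alone do not account for the rise from 12 to 171 for PARPi, while the full combination went from 4384 to 3039. The main fit shares 1 estimate of spread per gene over groups of unequal spread, so counts of different comparisons are not like for like. Otherwise the cause was not tested. Counts not given here stayed within 1.5 times that of edgeR. Depth limits the folds of genes with few counts, such as Chil3 at 0.242 ± 0.144 CPM in controls.

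With 1 library left out, counts ran from 0 to 5 for PARPi, 72 to 316 for ICB, 1337 to 2596 for PARPi+ICB, 1991 to 3171 for PARPi+anti-VEGFA, 2877 to 4143 for the full combination, 26 to 293 for ICB added to PARPi, 0 to 205 for anti-VEGFA added to PARPi, 0 to 1 for anti-VEGFA added to PARPi+ICB, 0 to 72 for ICB added to PARPi+anti-VEGFA and 0 to 2 for the interaction of PARPi and ICB. A group of 3 then held 2 animals, and the cause was not tested.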

Other observations

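The tests of this part were chosen after the results were seen, other than the adjustment for adipocyte genes. The constant regions of the immunoglobulin heavy chains, also chosen after their values were seen, are given here by treatment, and whether their changes differ from each other was not tested. Ighm (mu) stood at 1023 ± 338 CPM in controls, 1035 ± 249 with PARPi, 1844 ± 515 with PARPi+anti-VEGFA, 5668 ± 2888 with ICB, 13879 ± 5051 with PARPi+ICB and 9402 ± 3719.6 in the full combination. Igha (alpha) stood at 1416 ± 425, 5930.3 ± 1959, 6576 ± 1490.1, 4195 ± 1796, 5815 ± 2853 and 6269.7 ± 4451 CPM in the same order. When ICB was added to PARPi, Ighm changed by 3.74 ± 0.44 (edgeR adjusted p 0.00106), Ighg1 by 1.83 ± 0.91 (0.331), Ighg3 by 1.63 ± 0.92 (0.397), Ighe by 0.79 ± 0.78 (0.671), Ighd by 0.36 ± 0.63 (0.828), Igha by -0.028 ± 0.57 (0.989), Ighg2b by -0.38 ± 0.54 (0.785) and Ighg2c by -0.22 ± 0.58 (0.896). Against controls, Igha changed by 2.07 ± 0.59 with PARPi (0.165), 1.57 ± 0.58 with ICB (0.167), 2.04 ± 0.59 with PARPi+ICB (0.0258), 2.21 ± 0.58 with PARPi+anti-VEGFA (0.0135) and 2.15 ± 0.57 in the full combination (0.0119). The interaction of PARPi and ICB on Ighm was 1.27 ± 0.56 (0.958), and that of anti-VEGFA and ICB -1.39 ± 0.52 (0.642).

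Genes of T cells and other immune cells stood higher in the 3 combination arms, PARPi+ICB, PARPi+anti-VEGFA and the full combination, than in controls. A lower share of tumour RNA, which would raise all other cell types alike, is argued against only as the whole cause. The median of T cell genes lay above that of pericyte genes in each arm by at least 1.11, with or without a covariate. The SE of 0.26 is over the genes of the lists and does not measure the spread between animals. Per animal, pericyte genes averaged 4.57 to 4.94 log2 CPM in controls and at most 4.11, 4.44 and 4.31 in the 3 arms. A part played by tumour share is not excluded, because an effect of treatment on pericytes would widen the gap. The fall of pericyte genes is not kept, as 7, 5 and 8 were called without a covariate and 0 in each arm with the adipocyte score or the quality RNAs (medians -0.80, -0.58 and -0.73, then -0.60, -0.31 and -0.46 and -0.38, -0.082 and -0.54, with median SE 0.19, 0.17 and 0.17, then 0.24, 0.25 and 0.27 and 0.27, 0.32 and 0.22). With the adipocyte score as covariate, 13 of 15 T cell genes, the fewest of the 3 arms, stayed called. Their medians were 1.42, 1.19 and 1.65 against 1.40, 1.09 and 1.51 without it, and their median SE 0.29, 0.29 and 0.33. However, the score lay above all controls in each library of the 3 arms (at least 1.73, 0.988 and 1.94 against at most 0.380 log2 CPM). More fat tissue around the tumour therefore cannot be told apart from treatment by this covariate. Called macrophage genes went from 9, 9 and 9 to 4, 4 and 3 with the score. The counts of all called genes then fell to 1204, 814 and 800, called cytotoxic genes from 10, 9 and 10 to 5, 3 and 4 (medians 1.53, 1.43 and 1.75 to 1.52, 1.31 and 1.67, as the median SE rose from 0.40, 0.39 and 0.39 to 0.51, 0.49 and 0.57), and called MHC class I genes from 8, 10 and 10 to 1, 1 and 0 with smaller changes (medians 0.52, 0.52 and 0.56 to 0.38, 0.38 and 0.40). A difference in library quality was read from Rn7sk, Lars2 and Mir6236. With their mean as covariate, 15 of 15 T cell genes stayed called in the full combination, 9 in PARPi+ICB and 0 in PARPi+anti-VEGFA. In the full combination the T cell median stayed above 3 times the median SE, while called MHC class I genes went from 10 to 5. Rn7sk and Mir6236 reached control levels there only in full-combination replicate 4 (2.83 and 97.0 CPM, against at least 1.83 and 76.8 in controls). Its other libraries ran from 0.584 to 1.04 and from 22.2 to 69.2 CPM, and Lars2 lay below all controls. For T cell genes in that arm this argues against library quality as the whole cause, but it rests on 1 library and does not exclude it. In PARPi+ICB and PARPi+anti-VEGFA library quality cannot be told apart from treatment, since all 3 RNAs lay below all controls and the SE rose. In the order of the arms, medians were 1.35, 1.03 and 1.47 against 1.40, 1.09 and 1.51 without the covariate. The median SE was 0.33, 0.39 and 0.26 against 0.22, 0.21 and 0.21. The counts of all called genes went from 2922, 3228 and 4384 to 630, 0 and 2471.

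Plasma cell genes stood higher with ICB than in controls, where Rn7sk, Lars2 and Mir6236 were lower in all 3 ICB libraries than in all 3 controls. With the mean of these 3 RNAs as covariate, edgeR called 0 of 10 plasma cell genes in place of 8 and 0 genes in all in place of 400, while the plasma cell median went from 1.61 to 1.71 and its median SE from 0.35 to 0.59. A difference in library quality and an effect of ICB cannot be told apart here, because the 3 RNAs follow the groups.

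Chil3, Retnla, Il5ra and Ighm stood higher where ICB was given, with PARPi+ICB replicate 3 and ICB replicate 3 holding most of the Chil3 and Retnla of their groups, but Retnla and Il5ra were not called for ICB against control (edgeR adjusted p 0.0625 and 0.141). For Chil3 and Ighm, 10 of 10 libraries with ICB lay above all 10 without it, but 9 for Il5ra and 8 for Retnla. Retnla had a lowest value of 1.86 CPM with ICB and a highest of 5.69 CPM without. Pancreatic acinar RNA, as the whole cause, is argued against for ICB added to PARPi, since its list averaged at most -1.76 log2 CPM in PARPi+ICB libraries while the 4 genes rose, and for ICB added to PARPi+anti-VEGFA, where the list averaged 1.81 ± 4.46 without ICB and 0.57 ± 4.93 with it, and the log2 changes were 6.77 ± 0.86, 4.26 ± 0.77, 3.00 ± 0.50 and 2.35 ± 0.36 with and 6.75 ± 0.92, 3.63 ± 0.74, 2.30 ± 0.58 and 2.25 ± 0.43 without the libraries that hold acinar RNA, the smallest 3.99 times its SE, although 3 of the 4 calls ended with 5 of 8 libraries left. For ICB against control, where ICB replicate 3 holds acinar RNA, it is argued against as the whole cause for Chil3 (log2 6.27 ± 1.12 to 4.24 ± 0.98) and Ighm (2.47 ± 0.41 to 2.02 ± 0.39), each at least 4.31 times its SE without the libraries that hold it, but cannot be told apart for Retnla (3.68 ± 1.00 to 1.78 ± 0.90) and Il5ra (1.70 ± 0.59 to 1.30 ± 0.59), the smaller 1.99 times its SE with 2 ICB libraries left. More eosinophils, with 5 of 8 marker genes tested and medians of 1.07 and 0.91 for ICB added to PARPi and to PARPi+anti-VEGFA (larger fry adjusted p 0.112), more mast cells, with 9 of 9 tested and medians of 0.80 and 1.21 (fry adjusted p 0.0894 and 0.0147), and more alternatively activated macrophages, with medians of 0.84 and 0.22 (fry adjusted p 0.0454 and 0.840), cannot be told apart, because each list missed the threshold in at least 1 of the comparisons with 3 or 4 animals per group, and for ICB against control the 3 medians were 0.85, 0.074 (5 of 9 positive) and 0.61 (fry adjusted p 0.112, 0.939 and 0.112). Mcpt1, a mast cell protease chosen after its values were seen, stood at 1.69 ± 0.526 CPM with PARPi, 14.6 ± 8.58 with PARPi+ICB, 2.28 ± 1.53 with PARPi+anti-VEGFA and 8.22 ± 2.18 in the full combination.

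Other splits of the same libraries into groups of the same sizes were tried for each count of called genes. For PARPi+anti-VEGFA against control, 1 of 35 splits, the real one, reached 3228 genes (highest other 1145). For the full combination 1 of 35 reached 4384 (highest other 2195), and for anti-VEGFA added to PARPi 1 of 35 reached 104 (highest other 27). Each share is under 0.05, but it is the smallest that 35 splits can give and was not corrected for the number of comparisons. These splits argue against chance for each of the 3 counts taken alone, but do not exclude it. With 1 library left out, the count of 104 ranged from 0 to 205. For PARPi (12 genes, highest other 0), ICB (400, highest other 0), PARPi+ICB (2922, highest other 1) and ICB added to PARPi (229, highest other 0), 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. For ICB added to PARPi+anti-VEGFA, 2 of 35 splits reached 16 genes, and chance cannot be excluded. Its highest other split called 92, several times the real count, which points to a structure of these samples that was not identified. For anti-VEGFA added to PARPi+ICB edgeR called 0 genes, so each of the 35 splits gave at least as many by definition (highest other 1) and they decide nothing. There, 745 genes had an unadjusted p under 0.05, DESeq2 called 12 and limma 2. The 40 splits of each interaction decide nothing for the same reason, as edgeR called 0 genes. Their highest others were 571 for PARPi by ICB and 259 for anti-VEGFA by ICB. Shuffling libraries over the groups can turn differences between treatments into interaction terms, so these highest counts are not read as a structure of the samples. For the 2 interactions, 946 and 1188 genes had an unadjusted p under 0.05, DESeq2 called 7 and 15 and limma 0 and 0.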
